A study of Mus musculus with 12 samples.

How the data were processed

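RNA-seq was carried out on 12 samples of sorted CD1d-tetramer-positive, YFP-positive iNKT1 cells of mice, in 4 groups of 3. Per the labels' protocols, total RNA was isolated with RNeasy mini kits and libraries were made with Nugen's Ovation Ultralow system. The submitters' processing notes name Trimmomatic 0.33, TopHat2 2.1.0, STAR, HTSeq 0.6.1, DESeq2 and the mouse genome build mm10, with no role or order given for them, so which aligner made the values is not given in the sources used here, nor whether counting used strand or how it treated reads shared by close copies of a gene.

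The authors deposited 1 table of 14004 Ensembl genes by 12 samples, used here as a signal that is never negative and was adjusted for library size. The values were not whole numbers, and the totals of the deposited columns lay between 21.4 M and 32.0 M (M, 1e6). Each column held steps of its own, the value of 1 read. The deposited values were matched by whole reads put through a negative binomial quantile adjustment to a common library size (fitted dispersion 1.42). Inverting that adjustment placed 96.9% of all values within 0.1 of a whole read, from 91.5% in control liver library 3 to 100% in cKO thymus library 1. At 0 to 4 reads the median value lay within 0.1 of a step of a whole multiple in 9 columns, 4 of which held a small value above 0 at 0 reads. In the other 3 it lay further off (by up to 0.138 of a step in cKO liver library 1, 0.183 in cKO liver library 2 and 0.176 in control liver library 3), and their reads rest on the inversion alone. That the authors used this adjustment is inferred from the values and is not stated in the sources used here. Recovered reads gave the depth of each library, the read numbers behind low values and the reads for edgeR and DESeq2; the main tests used the deposited values.

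Gene symbols and positions were taken from an annotation of GRCm38, the assembly that mm10 names, by Ensembl identifier; 13359 identifiers (95.4%) matched and 645 did not and keep their identifier. Genes with a deposited value of at least 10 in at least 3 libraries were tested (13058), and 946 were left out. Differences were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), in 1 model with a mean for each of the 4 groups, a trend of variance with expression and no covariate (8 residual and 10.7 prior degrees of freedom). P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Contrasts were cKO against control in thymus, in liver and over both tissues, the difference of the genotype effects (liver minus thymus), and liver against thymus in control and in cKO cells. The plan named edgeR's quasi-likelihood test if the table held whole counts; since the values are an adjusted signal, limma was used as the plan set out for that case.

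A set of 34 gene lists was fixed, of which 29 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with adjustment over the lists of a contrast. The lists cover effector, receptor and signalling genes of T and NK cells, iNKT subsets, the cell cycle, metabolism and stress, and markers of other cells that a sort could hold. Some lists share members, such as Gzma and Gzmb in the terminal effector and cytotoxic lists, so their tests are not independent. Members are counted as rising or falling over all tested genes and again adjusted over the list alone. Groups, tests, lists, most alternatives and the rule for named genes were set before the data were examined. The rule named Ets1 and Tbx21 in every sample, and for both genotype contrasts and the tissue contrast in control cells the 10 largest rises and 10 largest falls among called genes with a mean of at least 50 in the higher group and no overlap of libraries. It left out predicted genes, Rik genes, pseudogenes and antigen receptor segments. For the interaction it named up to 10 called genes by smallest adjusted p, and for each list up to 4 called members and up to 2 others with the highest mean. Where a group had 0 reads in all libraries, the fold is a lower bound against a floor of 3 reads per library; where it had 1 to 3 reads, the ratio of read shares is given with an exact conditional binomial interval (95%).

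The scripts were tested on simulated counts with a seeded set of changed genes drawn from the real means and depths. In the thymus contrast (12999 genes simulated) limma recovered 1.5% of genes changed 2-fold, 16.4% changed 4-fold and 45.5% changed 16-fold, with 5 false calls among 47; in the liver contrast (13001 genes) 0%, 14.9% and 54.5%, with 4 false among 50; and in the interaction (13023 genes) 0%, 1.5% and 22.7%, with 0 false among 16. A simulated 4-fold change of the cytotoxic list in liver gave a camera adjusted p of 1e-49 with 1 other list called, and no change gave 0.4 with 0. Genes not called may therefore have changed by several fold. Simulated genes varied independently of each other, and each had the same dispersion in every library. The simulation thus does not show how list tests fare with correlated genes, or gene tests with a noisier group. Alternatives were other pseudocounts, filters and scalings, array quality weights, a robust trend, a minimum fold, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, only the 6 libraries compared, the replicate number as a block, each library left out in turn and, for lists, an estimated correlation and fry. Leaving out the 2 libraries under 5 M reads, or control thymus libraries 1 and 2, was added after the data were seen, as were list tests for the contrasts over both tissues, of the interaction and in cKO cells.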

Results

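RNA-seq was carried out on invariant natural killer T cells of the type 1 subset (iNKT1), a CD1d-restricted T cell population defined by the transcription factor T-bet. Cells that bound CD1d tetramer and expressed a YFP reporter switched on by Cre recombinase under the Tbx21 (T-bet) promoter were collected from thymus and liver. The control genotype carried the Cre and the reporter. The conditional knockout (cKO) genotype carried floxed Ets1 alleles in addition, so that the transcription factor Ets1 was deleted in cells that had expressed Tbx21. Each of the 4 groups (control thymus, cKO thymus, control liver and cKO liver) held 3 libraries, 12 in all. The design text calls them independent replicates, but the labels do not say whether they came from separate mice. The p-values thus measure the spread between these samples, which may be technical. That spread is 1 estimate per gene over all 4 groups, so a noisier group can get p-values that are too small.

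Reads recovered from the deposited values came to between 18.5 M and 43.4 M (M, 1e6 reads) in 10 libraries. Control liver library 3 had 3.87 M and cKO liver library 2 had 3.21 M. One read was worth between 0.615 and 6.662 deposited units, the latter in the library with the fewest reads. Control thymus libraries 1 and 2 had 3528 and 2824 genes without a read, against 1782 in control thymus library 3 and 1415 to 2176 in the cKO thymus libraries. Mitochondrial ribosomal RNA made up between 23.2% and 34.2% of the deposited values of a library. Its share was 30.0% and 34.2% in control thymus libraries 1 and 2, against 24.2% to 25.8% in the other thymus libraries. In liver it ran from 23.2% to 33.1%. A higher share leaves less of a column's total to other genes. Whether this uneven share shifted the thymus contrast was not tested. All group values below are means ± SD of the authors' adjusted values over 3 libraries (n = 3), and fold changes are limma estimates on log2(value + 1) ± SE, which average the logarithms of single libraries and so are not the ratio of the group means printed beside them.

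**Figure D1:**
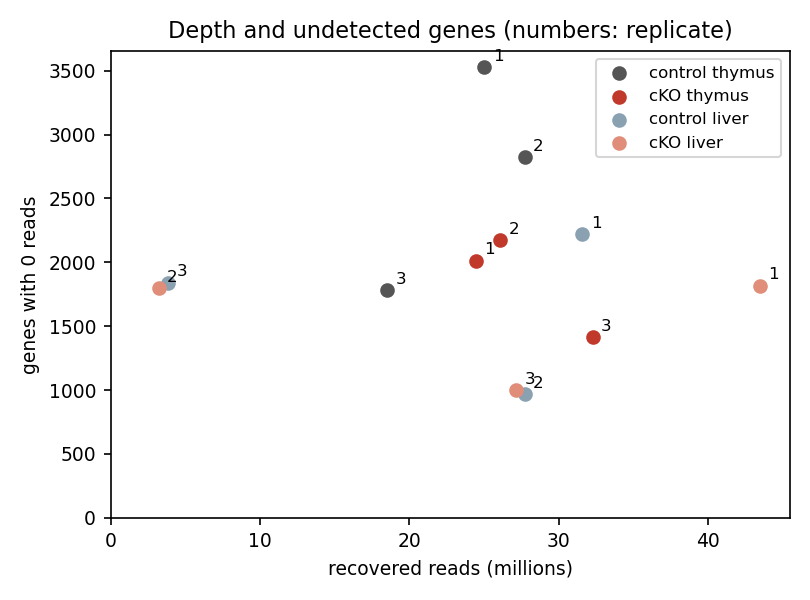
Number of genes with 0 reads (y) against reads recovered, in M (1e6 reads, x), for the 12 libraries by group. Each point is 1 library, labelled with its replicate number. Control liver library 3 (3.87 M) and cKO liver library 2 (3.21 M) had far fewer reads than the rest. Control thymus libraries 1 and 2 had the most genes with 0 reads (3528 and 2824).

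Ets1 transcripts (ENSMUSG00000032035) were lower in cKO cells of both tissues (chromosome 9, 32636221 to 32757820, plus strand, GRCm38). The mean was 23745 ± 4279 in control thymus and 8225 ± 3176 in cKO thymus, a log2 fold change of -1.58 ± 0.27 (limma adjusted p = 0.0095). In liver it was 17737 ± 1587 in control and 4602 ± 1107 in cKO cells, a log2 fold change of -1.97 ± 0.27 (limma adjusted p = 0.0012). In each tissue all 3 cKO libraries lay below all 3 control libraries. The reads left in cKO cells are counts over the whole gene, which can include exons outside the floxed part. Tbx21 (chromosome 11, 97098071 to 97115331, minus strand), which the study's title asks about, had means of 3005 ± 2399.8 in control thymus, 4930.0 ± 1675 in cKO thymus, 2729 ± 679 in control liver and 5139.5 ± 1061 in cKO liver. Its log2 fold change was 0.95 ± 0.44 in thymus (limma adjusted p = 0.37), 0.92 ± 0.44 in liver (0.73) and 0.94 ± 0.31 over both tissues (0.15), so the higher means did not pass the test. The call of Ets1 in thymus was lost under 4 alternatives: without cKO thymus library 3 (log2 fold change -1.36, limma adjusted p = 0.072, within a range of 9.7e-05 to 0.8 over the alternatives), without control thymus libraries 1 and 2 (-1.31, 0.4), in the 6 thymus libraries alone (-1.58, 0.59) and with a replicate block within them (-1.58, 0.8). In liver it was lost without the 2 libraries under 5 M reads (0.059, within 4.2e-07 to 0.059). Tbx21 over both tissues passed the test without control thymus library 2 (limma adjusted p = 0.01) and without control thymus libraries 1 and 2 together (0.043), within a range of 0.01 to 0.43 over the alternatives.

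**Figure D2:**
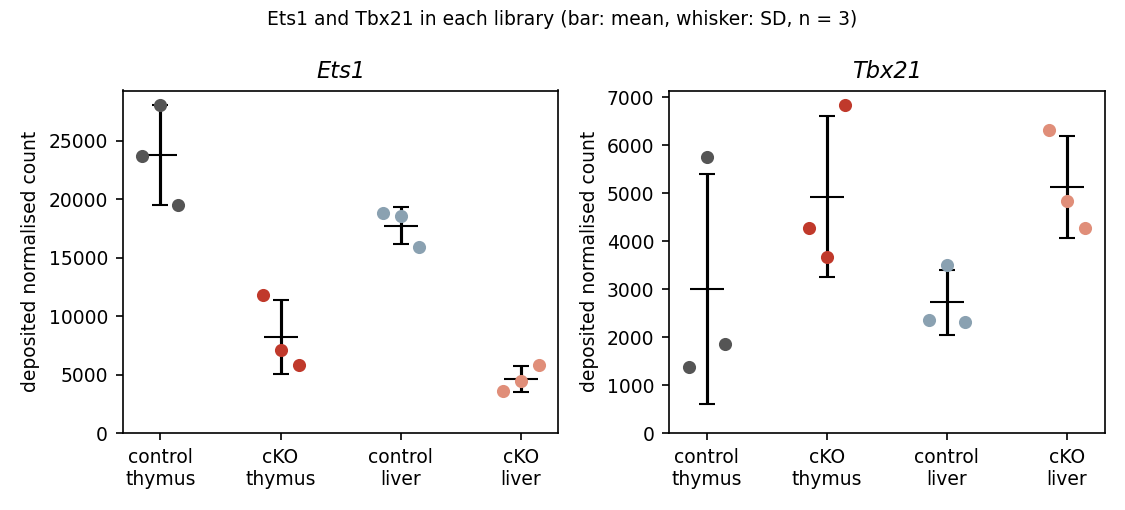
Deposited values of Ets1 and Tbx21 in each library, with points for the 3 libraries of a group and a bar for the group mean ± SD. Ets1 fell from 23745 to 8225 in thymus and from 17737 to 4602 in liver, while the differences in Tbx21 did not pass the test.

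The first comparison asked which genes differed between cKO and control iNKT1 cells in the thymus. Of 13058 genes tested, 83 passed an adjusted p of 0.05 in limma, 41 higher and 42 lower in cKO cells. The largest rise was that of Itgad, which encodes the integrin alpha D chain, at 299 ± 510.5 in control and 4512 ± 1448 in cKO thymus (log2 fold change 7.69 ± 1.72, limma adjusted p = 0.045). S1pr5, a sphingosine 1-phosphate receptor used by NK cells to leave tissues, was at 63.8 ± 104 and 1633 ± 1052 (6.97 ± 1.53, 0.043). Nebl rose by 7.01 on the log2 scale, the SUMO ligase gene Pias4 by 6.64, Mansc1 by 6.39, the ubiquitin ligase gene Rnf19b by 5.74, Gcnt2 by 5.66, Emb by 5.6, Dzank1 by 5.51 and Trerf1 by 4.95. For all of these genes most control reads came from control thymus library 3, although Pias4 had only 5 reads over the control thymus libraries. Without control thymus libraries 1 and 2 none of these genes was called, and their log2 fold changes were 2.29 for Itgad, 2.87 for Nebl, 2.96 for S1pr5, 5.30 for Pias4, 3.36 for Mansc1, 1.97 for Rnf19b, 2.29 for Gcnt2, 2.87 for Emb, 2.36 for Dzank1 and 1.94 for Trerf1. The largest fall was that of A630023P12Rik, a gene of a class left out of the naming rule (log2 fold change -9.43), and the next that of Clec2i, a C-type lectin gene, from 1649.8 ± 767 to 6.56 ± 9.64 (log2 fold change -8.63 ± 1.16, limma adjusted p = 0.0022). A few genes were left with 1 to 3 reads over the cKO thymus libraries: the ratio of control to cKO reads was 560 for Cfap54 (95% counting interval 191 to 2720), 1070 for Ifi204 (191 to 42300) and 1250 for Mob3b (225 to 49600). Intervals of this kind and lower bounds of a fold cover counting error alone. Cd93, with 4 reads in cKO thymus, fell too (log2 fold change -7.86), as did Serpina3g (-7.53), Rasgrp2 (-6.87), Slfn5 (-6.81), Glipr2 (-6.17) and Gzma (-5.54). In all 83 genes the cKO and control libraries did not overlap, which was so for 14.5% of tested genes against 10% by chance. Here and in the contrasts below, this largely follows from calling genes in the same libraries and is no further support.

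Among cytotoxic effector molecules in the thymus, granzyme A and perforin fell while granzyme B rose. Gzma went from 4769.9 ± 2043 to 323 ± 403 (log2 fold change -5.54 ± 1.18, limma adjusted p = 0.038) and Prf1 from 1172 ± 964 to 28.2 ± 13.8 (-5.03 ± 1.04, 0.033). Gzmb (chromosome 14, 56258838 to 56262260, minus strand) went from 15591 ± 1817 to 33569 ± 6976 (1.09 ± 0.23, 0.039). These were 1 rise and 2 falls among 18 members over all genes, and 5 rises and 4 falls adjusted over the list alone. The list as a whole was not called (camera adjusted p = 0.85), and its median and mean differed in sign. Among called members of other lists, Stat4, which relays IL-12, fell (log2 fold change -1.64, limma adjusted p = 0.013), as did the IL-7 receptor gene Il7r (-1.80, 0.012), Cd38 (-4.75, 0.026) and Eno1, a glycolytic enzyme gene (-2.22, 0.044). The nuclear receptor gene Rora rose from 2683 ± 928 to 15218 ± 2048 (log2 fold change 2.56 ± 0.29, limma adjusted p = 4e-04). Further rises, given as log2 fold change and limma adjusted p, were those of Rasgrp1 (1.22, 0.0083), Ikzf3 (1.11, 0.043), Btla (2.0, 0.031), the gut-homing chemokine receptor gene Ccr9 (3.61, 0.0085), Itgb3 (3.08, 0.012) and Themis (2.76, 0.026). NK receptor genes of the Klr and Ly49 families showed no call among 21 members, of which 2 fell adjusted over the list alone (camera adjusted p = 0.15).

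Of 29 gene lists tested with camera in the thymus, 4 stood apart from other genes. Type I interferon response genes ranked lower in cKO cells (camera adjusted p = 0.0029), with 0 rises and 0 falls among 22 members, and 0 and 2 adjusted over the list alone. Terminal effector CD8 T cell genes ranked higher (0.028), with 2 rises and 1 fall among 20 members, and 8 and 1 adjusted over the list alone. The genes called were Gzmb and S1pr5, which rose, and Gzma, which fell. Circulation and egress genes ranked higher (0.035), with 1 rise and 0 falls among 14 members, and 5 and 0 adjusted over the list alone. Cell cycle genes ranked higher (0.035) with 0 rises and 0 falls among 30 members, and 0 and 0 adjusted over the list alone. Immature thymocyte markers, of which Themis was the 1 of 9 members called (8 positive; 1 rise and 0 falls adjusted over the list alone; camera adjusted p = 0.14), made up between 0.0159% and 0.0234% of the values in the cKO thymus libraries and between 0.00379% and 0.0128% in the control thymus libraries. In the liver libraries their share was between 0.0205% and 0.0336%. With an estimated correlation none of the 4 lists that stood apart was called: adjusted p = 0.43 with an estimated correlation for the interferon, terminal effector and circulation lists, and adjusted p = 0.69 with an estimated correlation for cell cycle genes. The medians and means of the effector cytokine, inhibitory receptor, tissue residency, ETS family and B cell marker lists did not share the sign of each other or of their test, and none of these lists was called. The count of gene lists went to 2 without control thymus library 1 or without control thymus library 3.

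The median log2 fold change of all tested genes in the thymus was 0.236 as deposited and 0.003 after rescaling by the trimmed mean of M-values (TMM), under which 28 genes rose and 80 fell. The split was 31 and 58 after median-of-ratios rescaling. Gzmb (log2 fold change 0.83 after TMM, limma adjusted p = 0.14) and Ikzf3 (0.85, 0.15) then lost their calls, within ranges of 0.0072 to 0.8 and 0.0089 to 0.8 over their alternatives, and Pias4 lost its call under quantile normalization (0.077). Gzmb also lost its call without control thymus library 1 (log2 fold change 1.07), control thymus library 2 (1.18), cKO thymus library 1 (0.96) or cKO thymus library 3 (1.05). The number of genes called was 43 without control thymus library 1, 43 without control thymus library 2, 541 without control thymus library 3, and 27, 43 and 21 without cKO thymus libraries 1, 2 and 3. Among the 34 genes named as called, Clec2i, Cfap54, Rora and Rasgrp1 kept their calls without each library in turn, and the rest lost theirs without at least 1. Fitted to the 6 thymus libraries alone, limma called 0 genes (952 at an unadjusted p under 0.05), edgeR and DESeq2 on recovered reads of all 12 libraries called 51 and 613, and 4 genes were called without control thymus libraries 1 and 2.

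In the liver, the same comparison called 66 genes, 41 higher and 25 lower in cKO cells. Gzmb rose from 8048 ± 2173 to 57648 ± 13074 (log2 fold change 2.85 ± 0.23, limma adjusted p = 1.5e-06). Styk1, a receptor-like kinase gene on chromosome 6 (131299142 to 131353597, minus strand), went from 2.29 ± 3.23, 7 reads over the 3 control libraries, to 2656 ± 959 (10.06 ± 0.70, 2.1e-07). Itgad again rose, from 7.24 ± 6.64 to 3587 ± 636 (9.43 ± 1.72, 0.012). The transcription factor gene Zeb2, which acts with T-bet in terminal effector differentiation, rose from 49.95 ± 51.7 to 5891 ± 2429.5 (7.47 ± 1.47, 0.022). The Ly49 receptor genes Klra1 and Klra4 rose from 400.3 ± 109.6 to 4565 ± 658 and from 191 ± 128 to 2230.3 ± 566 (log2 fold changes 3.54 ± 0.38 and 3.71 ± 0.58, limma adjusted p = 1e-04 and 0.0032). Ly49 genes are close copies of each other, and how the counting treated shared reads is not given in the sources used here, so the split between them is uncertain, as it is among the Ifi20 and Serpina3 families. The calls of Styk1, Gzmb, Klra1, Izumo1r and Atp2b4 held under every alternative run, with a highest limma adjusted p of 0.00061, 8.7e-05, 0.007, 0.014 and 0.017.

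Further large rises in the liver were those of genes with few or no reads in control cells. Lgi4, Tmtc1, Fxyd7 and Fcrl6 had 0 reads in all 3 control liver libraries and were at least 135-fold, 89.5-fold, 75.2-fold and 43.7-fold higher in cKO liver, against a floor of 3 reads per library. The unnamed gene ENSMUSG00000086878 had 1 read in control liver (ratio 10300, 95% counting interval 1850 to 408000) and Pde8b had 3 (609, 208 to 2960). Nhsl2 rose by 9.33 and P3h4 by 7.80 on the log2 scale. Among the falls, Mmp9, a matrix protease gene abundant in neutrophils and the 1 of 12 fixed neutrophil markers present in the table, stood at 3349 ± 284 in control liver and had 2 reads in cKO liver (ratio 4710, 1300 to 38900), while ENSMUSG00000039309 also kept 2 reads (776, 214 to 6420). Plxnd1, at 0 reads in cKO liver, was at least 43.6-fold lower. Cd93 fell from 2548 ± 505 to 16.8 ± 22.2, Izumo1r, which encodes folate receptor 4, from 2608 ± 701 to 18.02 ± 15.6, and the calcium pump gene Atp2b4 from 3573 ± 527 to 119 ± 50.7. The chemokine gene Xcl1 fell from 3901 ± 609 to 695 ± 268 (log2 fold change -2.54 ± 0.42, limma adjusted p = 0.0062), and falls were also called for Rassf2 (-3.94), Ifi213 (-2.81) and Gpr132 (-2.74). Cd93 and Plxnd1 are also expressed in endothelium. Of 12 endothelial markers 1 could be tested: Pecam1 had a mean of 583.9 in control and 40.03 in cKO liver and was not called (log2 fold change -4.98, limma adjusted p = 0.35, and 0.01 adjusted over the list alone, which with 1 member is the unadjusted p), as in thymus (-4.37, 0.28 and 0.022). The 3 endothelial markers in the table summed to between 466 and 946 in the control liver libraries and between 1.16 and 89.7 in the cKO liver libraries, and to between 72.95 and 302 in control and 0.923 and 68.5 in cKO thymus. In all 66 genes the libraries of the 2 groups did not overlap, which was so for 18.6% of tested genes.

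**Figure D3:**
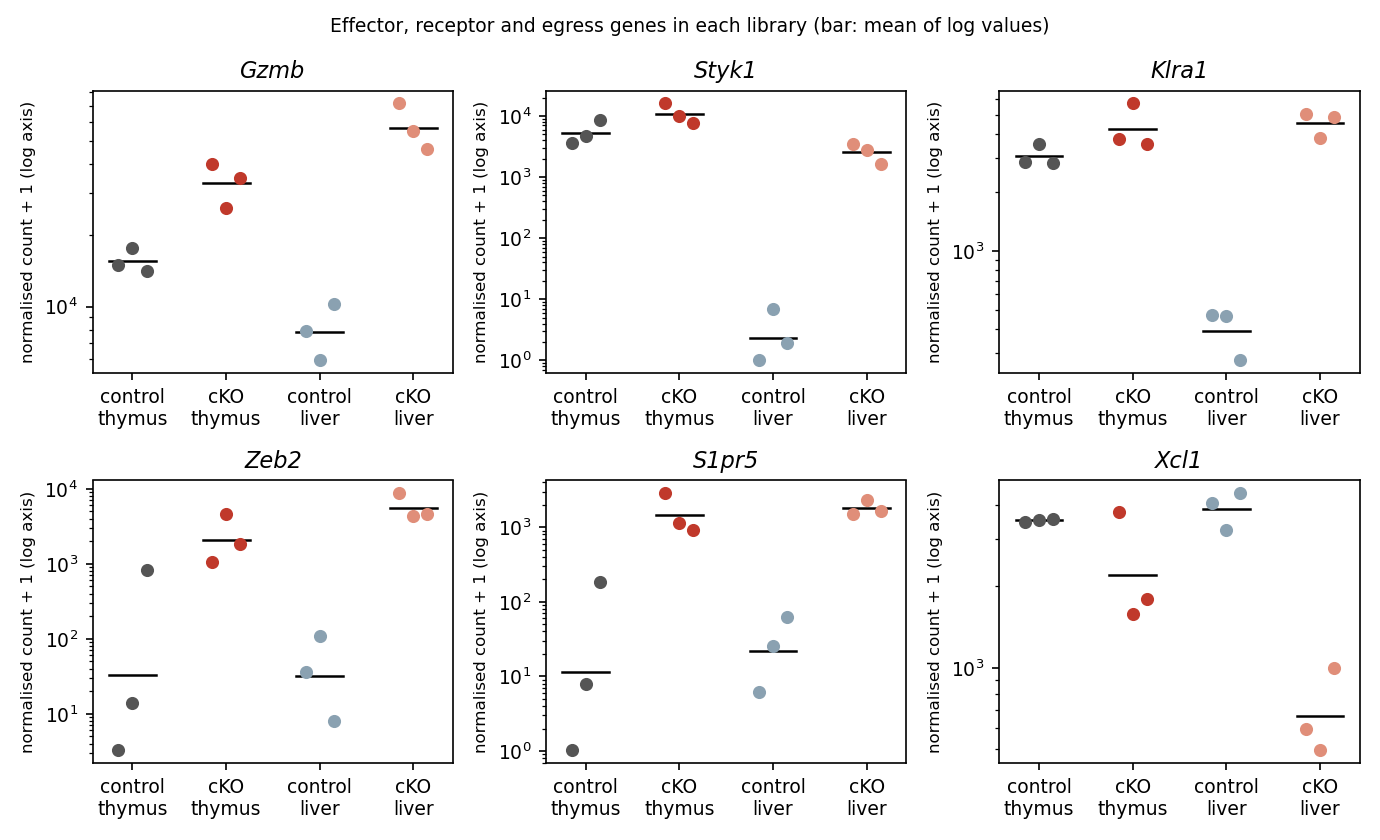
Deposited values plus 1, on a log axis, of 6 genes in each of the 12 libraries by group. Gzmb, Styk1, Klra1, Zeb2 and S1pr5 were higher and Xcl1 lower in every cKO liver library than in every control liver library; in liver S1pr5 was not called (limma adjusted p = 0.065).

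As a group, terminal effector CD8 T cell genes ranked higher in cKO liver cells (camera adjusted p = 9.6e-18, adjusted p = 0.0019 with an estimated correlation), with 6 rises and 0 falls among 20 members, and 13 and 1 adjusted over the list alone. Besides Gzmb and Zeb2 the members that rose included S100a4 (3.53, limma adjusted p = 0.0063), the lectin gene Lgals3 (5.90, 0.0098) and Vim (2.33, 0.018), given as log2 fold changes, while Cd44 was at 16321 ± 4133 in control and 6460.0 ± 669 in cKO liver (limma adjusted p = 0.066). Circulation and egress genes ranked higher too (camera adjusted p = 4.1e-08, adjusted p = 0.01 with an estimated correlation), with 2 rises and 0 falls among 14 members, and 7 and 0 adjusted over the list alone. The called members were S1pr1, the receptor for egress into blood, from 310.3 ± 169.5 to 3355 ± 1499 (log2 fold change 3.53 ± 0.60, limma adjusted p = 0.0067), and Itgb1 (1.02 ± 0.23, 0.047). The circulation list shares Cx3cr1, S1pr5 and Ly6c2 with the terminal effector list, so their results are not independent. Cytotoxic effector molecules ranked higher (camera adjusted p = 9e-04, adjusted p = 0.051 with an estimated correlation), with 1 rise and 1 fall among 18 members, and 5 and 1 adjusted over the list alone: Gzmb rose and Tnfsf10, which encodes the death ligand TRAIL, fell (-2.14 ± 0.40, limma adjusted p = 0.014). Nkg7 was at 22881 ± 2043 in control and 38267 ± 8318 in cKO liver and was not called. Tissue residency genes ranked lower (camera adjusted p = 0.0024, adjusted p = 0.051 with an estimated correlation), with 0 rises and 1 fall among 20 members, and 0 and 6 adjusted over the list alone. Xcl1 was the member called, and Cxcr6, the receptor of liver iNKT cells for CXCL16, was at 39191 ± 1450.3 and 24129 ± 1732 (limma adjusted p = 0.17).

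Cell cycle genes ranked higher in cKO liver cells without a called member, with 29 of 30 members on the higher side (camera adjusted p = 4.1e-08, adjusted p = 0.23 with an estimated correlation; 0 called adjusted over the list alone). Mki67, the proliferation marker, was at 6133 ± 2028 in control and 18714 ± 11934 in cKO liver (limma adjusted p = 0.28). Type I interferon response genes ranked lower (camera adjusted p = 0.013, adjusted p = 0.37 with an estimated correlation), again with 0 of 22 members called over all genes or adjusted over the list alone. B cell markers ranked lower (camera adjusted p = 0.021, adjusted p = 0.23 with an estimated correlation), with 0 rises and 1 fall among 6 members, and 0 and 1 adjusted over the list alone: Ighm went from 6512 ± 1105 to 1468 ± 465 (limma adjusted p = 0.024). B cell markers made up 0.21% of the values in control liver library 1 and 0.0563% in cKO liver library 1, against at most 0.0296% in the other libraries. NK receptor genes of the Klr and Ly49 families held 2 rises and 0 falls among 21 members, and 3 and 1 adjusted over the list alone (camera adjusted p = 0.089, adjusted p = 0.39 with an estimated correlation). Slamf7 (1.06, limma adjusted p = 0.033) and Ikzf2 (1.88, 0.03) rose, and the chemokine gene Ccl5 was at 6599 ± 1278 and 18156 ± 3725 without passing (1.45, 0.22). The median and mean of the iNKT2, inhibitory receptor, coreceptor, cytokine receptor and other NK receptor lists differed in sign, and none of these lists was called.

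**Figure D4:**
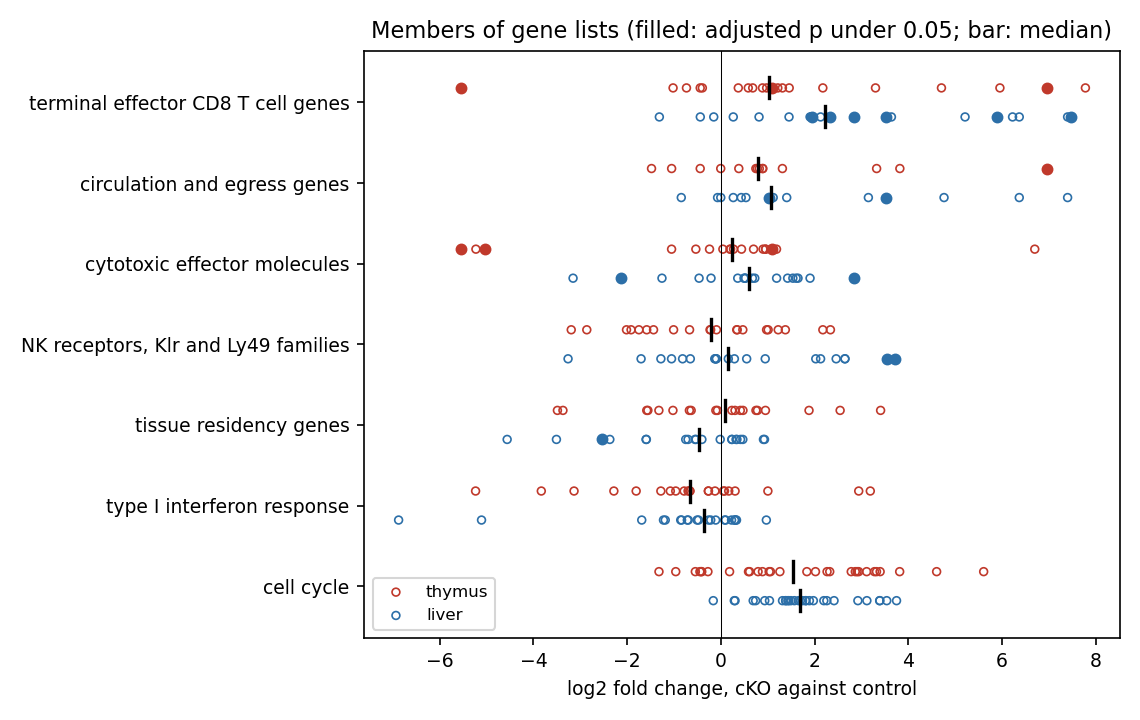
Fitted log2 fold changes, cKO against control, of the tested members of 7 gene lists in thymus (red) and liver (blue); each point is a gene. Terminal effector and circulation genes lie mostly above 0 in liver, and type I interferon genes mostly below 0 in both tissues.

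The number of genes called in the liver was 36, 32 and 35 without control liver libraries 1, 2 and 3 and 31, 21 and 30 without cKO liver libraries 1, 2 and 3, and 7 without the 2 libraries under 5 M reads. Of the 34 genes named as called, 11, among them Ets1, Gzmb, Styk1, Mmp9 and Klra4, kept their calls without each library in turn, and the rest lost theirs without at least 1. Zeb2 lost its call without any one of 5 libraries, all but control liver library 2, at log2 fold changes of 6.47 to 7.65, and S1pr1 without cKO liver library 1 (3.19). Quantile normalization called 191 genes, 98 higher and 93 lower, DESeq2 called 273 and edgeR 39, and array weights 620. Slamf7 and Itgb1 lost their calls under TMM (limma adjusted p = 0.065 and 0.07, within ranges of 8.7e-04 to 0.3 and 4.9e-04 to 0.22 over their alternatives).

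Genes called in both tissues all moved the same way: 5 rose and 7 fell, against 0.13 and 0.08 expected of independent lists of these sizes, and none moved in opposite directions. The thymus and liver contrasts share no library, but both come from 1 model with a common error variance for each gene. A gene of low variance is more easily called in both, so the expected numbers may be too low. Besides Gzmb and Itgad, the neuropilin gene Nrp2 (log2 fold change 3.92 in thymus and 5.97 in liver), Aplp2 (2.82 and 2.29) and the scaffold gene Ahnak (1.0 and 1.35) rose. Besides Ets1 and Cd93 (-7.86 and -8.24), the falls were those of Rcbtb2 (-1.91 and -2.39), the lysophosphatidic acid receptor gene Lpar6 (-1.80 and -2.02), Ifi203 (-1.71 and -1.35), Ifi213 (-2.77 and -2.81) and A630023P12Rik (-9.43 and -8.20). Those not named before were chosen after their values were seen. Of the genes called in thymus, 73 of 83 had the same sign in liver, and 64 of the 66 called in liver had the same sign in thymus, against 58.2% of all genes tested. Across all 13058 genes, which are not independent replicates, the fold changes of the 2 tissues correlated with Pearson's r = 0.281 and Spearman's rho = 0.227. Quantile normalization raised the number of genes called in both tissues from 12 to 32.

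**Figure D5:**
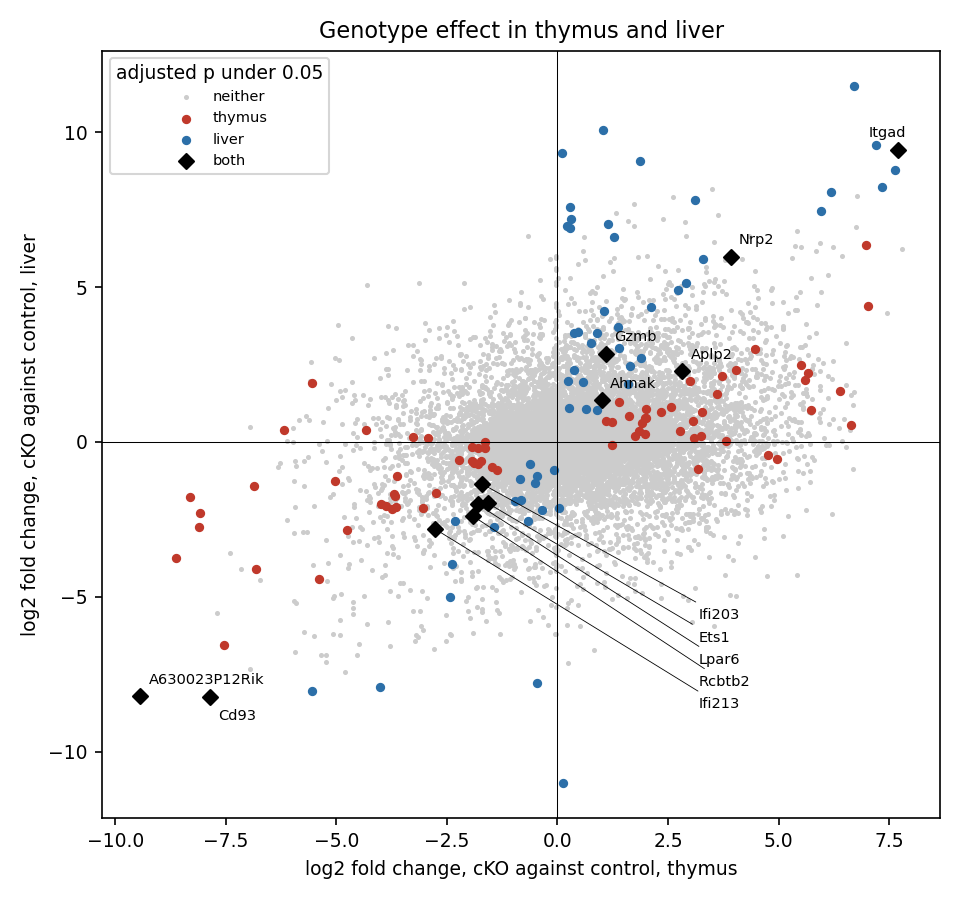
Log2 fold change, cKO against control, in liver (y) against thymus (x) for 13058 genes; red and blue points were called in thymus or liver, and the 12 labelled diamonds in both. The 12 genes lie in the upper right (5) and lower left (7) quadrants.

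A test of the genotype effect over both tissues called 297 genes, 154 higher and 143 lower. The smallest adjusted p-values were those of Gzmb (log2 fold change 1.97 ± 0.16, limma adjusted p = 4.5e-06), Styk1 (5.55 ± 0.50, 6.7e-06) and Ahnak (1.17 ± 0.11, 9.3e-06), which were read off after their values were seen. Rora (1.85) and Klra1 (2.0) also rose, and the diacylglycerol kinase gene Dgka (-2.99), Atp2b4 (-3.71) and Clec2i (-6.19) fell. These values average both tissues, and those of Styk1 and Klra1 came mostly from liver. Klra1 had means of 3069 in control and 4330 in cKO thymus, against 400 in control and 4565 in cKO liver. Styk1 had means of 5642 and 11332 in control and cKO thymus, against 2.29 and 2656 in liver. Ets1 fell (log2 fold change -1.78 ± 0.19, limma adjusted p = 3.9e-05, held in 27 of 27 alternatives with limits of 3.6e-12 and 0.002). Gene lists tested for this contrast after the data were seen gave terminal effector genes (10 rises and 1 fall among 20; 11 and 1 adjusted over the list alone; camera adjusted p = 7.4e-10, adjusted p = 0.015 with an estimated correlation) and circulation genes (5 rises and 0 falls among 14; 8 and 1 adjusted over the list alone; 4.1e-06, adjusted p = 0.025 with an estimated correlation). Cell cycle genes (2.5e-06, adjusted p = 0.35 with an estimated correlation) and interferon genes (1e-04, adjusted p = 0.28 with an estimated correlation) were called with the preset correlation alone. TMM gave 130 rises and 208 falls. The count was 546 without control thymus library 3, 193, 170 and 180 without control liver libraries 1, 2 and 3 and 183, 173 and 182 without cKO liver libraries 1, 2 and 3. It was 77 without the 2 libraries under 5 M reads, and DESeq2 on recovered reads called 753.

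Whether the genotype effect differed between liver and thymus was tested as an interaction. Styk1 was the gene called (log2 fold change of the difference 9.03 ± 0.99, limma adjusted p = 3.6e-04), and its call held in 27 of 27 alternatives with adjusted p between 3.4e-20 and 0.0078. Its means were 5642 ± 2621 in control thymus, 11332 ± 4308 in cKO thymus, 2.29 ± 3.23 in control liver and 2656 ± 959 in cKO liver. The control liver libraries held 0, 7 and 0 reads of Styk1, and the cKO liver libraries 5738, 422 and 1891. No other gene passed, with 702 at an unadjusted p under 0.05; edgeR called 3 and DESeq2 112. Neither Ets1 (-0.39 ± 0.39, limma adjusted p = 0.94) nor Tbx21 (-0.03 ± 0.63, 1) was called. Tests on lists, run after the data were seen, placed the members of the terminal effector (camera adjusted p = 3.9e-05), NK receptor (6.9e-04) and cytotoxic (0.015) lists higher in the liver than in the thymus effect, with 0 of 20, 21 and 18 members called. Rises and falls adjusted over the list alone were 5 and 0, 1 and 0, and 3 and 1. None held: adjusted p = 0.11 with an estimated correlation for the terminal effector list, and adjusted p = 0.17 with an estimated correlation for the NK receptor and cytotoxic lists. The count of genes was 9 without control thymus library 3.

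The same libraries gave the difference between liver and thymus in control cells. Styk1 was the largest fall, from 5642 in thymus to 2.29 in liver (log2 fold change -11.12 ± 0.70, limma adjusted p = 3.6e-08). Most NK receptor genes of the Klr and Ly49 families were lower in liver. Klrd1 (CD94) was at 16989 ± 3592 in thymus and 3352 ± 744 in liver (-2.34 ± 0.28, 3.5e-04), and Klra1 (-2.97), Klra5 (-4.27) and Klra9 (-5.39) fell too. The list held 0 rises and 6 falls among 21 members, and 2 and 14 adjusted over the list alone (camera adjusted p = 2.9e-16, adjusted p = 0.0066 with an estimated correlation). Its 3 positive members included Klrg1 (5.55) and Klrb1f (2.55), which were not called over all genes. The list of other NK-associated receptors did not fall, with a median of 0.73 and 1 rise and 0 falls among 14 members (camera adjusted p = 0.32). Il7r was at 39232 ± 11152 in thymus and 3638 ± 1352 in liver (-3.47 ± 0.32, limma adjusted p = 1.2e-05), and both IL-18 receptor chains fell (Il18r1 -2.81, Il18rap -1.25). Of 13058 genes 79 were called, 44 higher and 35 lower in liver, none with overlapping libraries (15.4% of tested genes had no overlap). Ets1 (-0.41, limma adjusted p = 0.56) and Tbx21 (0.12, 0.94) were not called.

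The chemokine receptor list ranked higher in control liver cells (4 rises and 1 fall among 13 members, and 5 and 2 adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.24 with an estimated correlation). Cxcr6 was at 16265 ± 4146 in thymus and 39191 ± 1450.3 in liver (log2 fold change 1.30 ± 0.21, limma adjusted p = 0.0031), and Ccr2 (1.29) and Ccr9 (4.04) were higher, while Ccr8 went from 5079 ± 4996 to 18.9 ± 31.9 (-9.61 ± 1.58). Members of the tissue residency list went both ways, with 2 rises and 2 falls among 20 members, and 6 and 6 adjusted over the list alone (camera adjusted p = 0.87): the E-cadherin-binding integrin gene Itgae fell from 5987 ± 2164 to 141 ± 209 (-6.75 ± 0.97, limma adjusted p = 0.0014) and so did Cdh1 (-8.54), while the ATP receptor gene P2rx7 rose from 469 ± 437 to 14462 ± 4255 (6.34 ± 0.98, 0.0027). The list's median and mean differed in sign. Mmp9, with 2 reads in control thymus, was the largest rise (ratio 4550, 95% counting interval 1260 to 37600). Pak6, Casp1, Tefm, ENSMUSG00000089672 and Kdelc1, with 0 reads in control thymus, were at least 191-fold, 144-fold, 113-fold, 64.9-fold and 57.2-fold higher, and Ms4a6d had 1 read there (ratio 1880, 336 to 74200). Tbccd1 (7.31), the interferon-induced chemokine gene Cxcl10 (7.17) and Enoph1 (7.13) also rose. Tgfa and Apol9a, with 0 reads in control liver, were at least 65-fold and 38.4-fold lower, and Fry (-7.63), Spsb1 (-7.55), Ptpn5 (-6.26) and Capg (-5.58) fell.

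Hepatocyte markers ranked higher in control liver cells, with 0 rises and 0 falls among 10 members, and 5 and 0 adjusted over the list alone (camera adjusted p = 0.0043, adjusted p = 0.17 with an estimated correlation). Their values summed to between 914 and 1967 in a liver library and between 23.7 and 869 in a thymus library. Dendritic cell and MHC class II genes ranked higher (camera adjusted p = 0.017, adjusted p = 0.39 with an estimated correlation), with 0 rises and 0 falls among 7 members, and 3 and 0 adjusted over the list alone. Cell cycle genes ranked higher (3.4e-05, adjusted p = 0.39 with an estimated correlation), with 0 rises and 0 falls among 30 members, and 7 and 0 adjusted over the list alone, as did effector cytokines and chemokines (0.035, adjusted p = 0.22 with an estimated correlation), with 0 rises and 0 falls among 15 members, and 1 and 0 adjusted over the list alone. Mitochondrially encoded genes ranked lower (4.7e-04, adjusted p = 0.39 with an estimated correlation), with 0 rises and 0 falls among 7 members, and 0 and 0 adjusted over the list alone. Without control thymus libraries 1 and 2 they ranked on the other side (camera adjusted p = 0.5). Other calls among list members were those of Emb (6.52), Rora (1.45), Itga4 (2.50), Itgb3 (2.50), Themis (3.50) and Il2rb (0.79), which were higher in liver, and Vim (-2.40) and Ctsc (-1.74), which were lower. Emb, Rora, Itgb3, Themis and Ccr9 were also called higher in cKO thymus. That contrast uses the same control thymus libraries, so these rises are not independent findings. The 2 contrasts called 11 genes higher and 1 lower in both, against 0.14 and 0.11 expected of independent lists (Pearson's r = 0.503 over all genes). Itga5, at 0 reads in control thymus, was at least 22.9-fold higher. TMM gave 38 rises and 65 falls and median-of-ratios 42 and 53, the median over all genes moving from 0.28 to 0.038 under TMM, and Il2rb, Ccr2 and Itgb3 then lost their calls. Quantile normalization kept 61 of the 79 calls, and Pak6, Tefm, Ms4a6d, ENSMUSG00000089672, Tbccd1, Kdelc1, Enoph1, Ctsc and Itga5 lost theirs. The number of genes called was 395 without control thymus library 3, 39, 27 and 30 without control liver libraries 1, 2 and 3, and 12 in the 6 libraries alone, while 4 lists were called without control thymus library 1. Of the 41 called genes under the naming rule, 18 kept their calls without each library in turn and 23 lost theirs without at least 1, among them Pak6, Tefm, Cxcl10, Tgfa, Cdh1 and Itga5. Styk1, Itgae, Capg, Klrd1, Klra5 and Il7r held under every alternative run, with a highest adjusted p of 0.048.

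In cKO cells the difference between liver and thymus was called for 29 genes, 14 higher and 15 lower in liver. The genes named were chosen after their values were seen, by smallest adjusted p. Ccl5 was at 1047 ± 96.6 in cKO thymus and 18156 ± 3725 in cKO liver (log2 fold change 4.10 ± 0.45, limma adjusted p = 3.5e-04). Izumo1r (-6.71 ± 0.96, 0.0068), Ctla2a (-2.61 ± 0.38, 0.0068), the cholesterol exporter gene Abca1 (-3.39 ± 0.55, 0.016), Il7r (-1.86 ± 0.32, 0.02) and Klrd1 (-1.56 ± 0.28, 0.024) were lower in cKO liver than in cKO thymus, and Nhsl2 (9.78 ± 1.61, 0.016) and Stat4 (1.70 ± 0.29, 0.02) higher. Both tissue contrasts called 4 genes higher and 7 lower in liver, against 0.05 and 0.04 expected of independent lists. The lists are not independent, since each gene has 1 error variance common to both contrasts. Lists tested after the data were seen gave NK receptors lower (camera adjusted p = 1.2e-07, adjusted p = 0.035 with an estimated correlation). They held 2 falls among 21 members, and 2 rises and 6 falls adjusted over the list alone. Circulation genes (camera adjusted p = 4.7e-05, adjusted p = 0.035 with an estimated correlation) and hepatocyte markers (2.4e-05, adjusted p = 0.035 with an estimated correlation) ranked higher. Of their 14 and 10 members 0 were called over all genes. Adjusted over the list alone, 4 rose and 0 fell for circulation genes, and 6 rose and 0 fell for hepatocyte markers. Ets1 (-0.8, limma adjusted p = 0.37) and Tbx21 (0.09, 1) were not called. The rest of the 11 lists called were lost with an estimated correlation. Quantile normalization gave 23 rises and 37 falls, and the count was 4, 4 and 13 without cKO thymus libraries 1, 2 and 3, 12, 9 and 3 without cKO liver libraries 1, 2 and 3, and 3 without both libraries under 5 M reads.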

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

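Tests of depth and of the authors' adjustment for Styk1, of the paralogs and the narrower stretch for NK receptors, and of the partial loss and the falls in thymus were chosen only after the result was seen, as were all list tests on the interaction. The effect of the genotype differed between tissues for Styk1 (log2 difference 9.03), and for the terminal effector list (camera adjusted p = 3.9e-05), the NK receptor list (0.00069) and the cytotoxic list (0.015), whose members were placed higher in the liver effect. The list differences did not hold with an estimated correlation, where camera called 0 of the lists. In splits of the libraries within each tissue, 10 of 100 gave at least the 1 gene called in the interaction, so chance was not excluded for that count. The highest count among them, 297, came from the split that exchanges the control and cKO liver groups, which turns the interaction into the effect over both tissues; the highest without it was 12.

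Styk1 had 0, 7 and 0 reads in the control liver libraries and 3220, 4079 and 6861 in control thymus. Depth is argued against, since the lowest cKO liver value was 89.6 times the highest floor of 3 reads in control liver. The call was kept on recovered reads (edgeR adjusted p = 0.00022, within limits of 3.4e-20 and 0.0078 over the alternatives). Those reads come from inverting the adjustment inferred here, so they cannot decide whether the authors' adjustment played a part. A lost stretch of chromosome 6 in the control liver samples stays open: the 5 other tested genes starting within 1 Mb (Klra2, Magohb, Ybx3, Klra3 and Klra1) had a median log2 fold change of 2.65, between 1.67 and 6.65, in cKO against control liver, as such a loss would predict. Klra1, Klra2 and Klra3, however, are Ly49 genes, a family in which Klra1 and Klra4 were called higher in cKO liver. A change of that family would give the same median, so the median cannot favour a loss. Outside the family, Magohb was at 2.55 and Ybx3 at 1.67. Against a complete loss, Ybx3 and Klra1 kept mean values of 883 and 400.3 in control liver, and the labels do not say whether thymus and liver cells came from the same mice. An effect of Ets1 on Styk1 that depends on tissue may also underlie it, and is untested.

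Most NK receptor genes of the Klr and Ly49 families were lower in control liver than in control thymus. Reads shared among Ly49 copies are argued against as the whole cause, since the 12 members outside the Klra family had a median of -1.13 with 3 called lower (Klra members: -3.42 over 9). NK cells among the sorted control thymus cells stay open, although the CD1d tetramer gate would remove them: 8 NK cell markers had a median of 1.43 in liver against thymus, over the bound set beforehand, but went both ways (-2.96 for Fcer1g to 6.69 for Ncr1, and a median of 1.43 with the member at 0 reads at its bound), so the median decides nothing. In control thymus Ncr1 had 0 reads, Eomes was at 8.36 and Tyrobp at 84.4, as few NK cells would leave, while the most abundant markers, Fcer1g (4759) and Klre1 (3293, also a member of the list), were lower in liver, as NK cells in the thymus would predict, and all 8 markers are also in other lists fixed here. A variant across the NK gene complex cannot be told apart from a difference in regulation. The other 76 genes of the interval had a median of 0.05, but 81.6% of them lie in 1 gap between members. The bound set beforehand was therefore wrong for this interval. The 6 others from Klre1 onward had a median of -2.52, of which 5 are pseudogenes. A difference between the tissues themselves also stays open. In cKO cells the list was lower in liver too, with a median log2 fold change of -1.56 over 21 members, 4 of them positive (camera adjusted p = 1.2e-07, adjusted p = 0.035 with an estimated correlation). The fall was thus not confined to control samples, and its cause was not tested.

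In control thymus libraries 1 and 2 more genes were without a read than in the other thymus libraries. Whether transcripts lost there account for rises called in cKO thymus stays open: 4.9% of them (2 of 41) had at most 3 reads in both libraries and more in library 3, but that bound, set beforehand, was too narrow, since in 41.5% (17 of 41, against 14.7% of genes tested) library 3 held at least 4 times the value of both others, and in 0 of them did library 1 or library 2 do so. For the falls, both libraries lay above every cKO thymus library in 100% (42 of 42), a value that decides nothing because no called gene had overlapping groups. The number of calls rests on these libraries, with 4 genes called without both and 541 without library 3. The loss of Ets1 is the difference the design names and also stays open, and these tests do not show that it explains each call.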

How the results depend on the processing

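Leaving out the 2 libraries under 5 M reads, or control thymus libraries 1 and 2, was chosen only after the results were seen, and the same holds for the list tests over both tissues, of the interaction and in cKO cells; the other alternatives were planned. Of 2695 values of named genes under alternatives, 1983 kept direction and side of the threshold, 690 lost a call, 2 gained one and 20 turned direction; of 198 list values 144 kept their call, 53 lost it and 1 turned. Of 177 counts 103 stayed within 1.5 times the reported count, and of 3 added list counts 0 did. Counts as reported were 83 for thymus, 66 for liver, 297 for both tissues, 1 for the interaction, 79 for tissue in control cells and 29 for tissue in cKO cells.

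These counts moved by more than 1.5 times, and the cause was not tested. Some fits below use fewer samples, yet some of their counts rose, as in liver (292 in the 6 libraries alone). The main model shares 1 estimate of spread over the 4 groups. Array quality weights, however, ran from 0.34 in control thymus library 1 to 2.97 in control liver library 2. The thymus count fell and the liver count rose both with these weights and in the 6 libraries of a tissue alone. A shared spread may thus give p-values that are too small in thymus and too large in liver. DESeq2 on recovered reads called 613 for thymus, 273 for liver, 753 for both tissues, 112 for the interaction, 478 for tissue in control cells, 263 for tissue in cKO cells; edgeR 51 for thymus, 39 for liver, 3 for the interaction, 49 for tissue in control cells, 18 for tissue in cKO cells. Array quality weights gave 28 for thymus, 620 for liver, 141 for tissue in cKO cells. Quantile normalization gave 191 for liver, 2 for the interaction, 60 for tissue in cKO cells, and 32 genes called in both tissues in place of 12. A pseudocount of 5 gave 106 for liver, 49 for tissue in cKO cells, a robust trend 100 for liver, and TMM 2 for the interaction. Fewer samples enter the rest: the 6 libraries alone gave 0 for thymus, 292 for liver, 12 for tissue in control cells, 57 for tissue in cKO cells (limma, 952 at an unadjusted p under 0.05 in thymus); without both libraries under 5 M reads 22 for thymus, 7 for liver, 77 for both tissues, 18 for tissue in control cells, 3 for tissue in cKO cells; and without control thymus libraries 1 and 2, where the lone control thymus library is assumed to vary like the other groups, 4 for thymus, 185 for both tissues, 29 for tissue in control cells. With each library left out in turn the counts ran from 21 to 541 for thymus, 21 to 36 for liver, 170 to 546 for both tissues, 1 to 9 for the interaction, 27 to 395 for tissue in control cells and 3 to 13 for tissue in cKO cells. The 541, 546 and 395 of thymus, both tissues and tissue in control cells and the 9 of the interaction came without control thymus library 3.

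Of the lists called with a preset correlation (4 in thymus, 7 in liver, 7 for tissue in control cells), camera with an estimated correlation called 0, 2 and 1, and of the added list tests 2 over both tissues, 0 in the interaction and 3 in cKO cells. Fry called 2 in thymus, 4 in liver and 5 for tissue in control cells, of which 1, 3 and 3 were among those lists. Leaving out a library gave 2 to 5, 5 to 9 and 4 to 8 lists, of which 1 to 4, 5 to 7 and 4 to 7 were among those reported. Mitochondrially encoded genes turned direction for tissue in control cells without control thymus libraries 1 and 2 (camera adjusted p = 0.5).

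Tbx21, not called in these comparisons, turned direction where its log2 fold change was near 0, and the cause was not tested. For tissue in control cells it was -0.15 with TMM, -0.02 with median-of-ratios, -0.15 with edgeR, -0.16 with DESeq2, and -0.29 to 0.73 with each library left out (-0.29 without control thymus library 1, -0.08 without control thymus library 3, -0.07 without control liver library 2). For the interaction it was 0.22 with TMM, 0.11 with median-of-ratios, 0.21 with edgeR, 0.24 with DESeq2, and -0.64 to 0.39 with each library left out: 0.39 without control thymus library 1, 0.17 without control thymus library 3 or control liver library 2, 0.23 without cKO thymus library 3, 0.01 without cKO liver library 2 and 0.1 without cKO liver library 3. For tissue in cKO cells it was -0.07 with array weights and -0.09 to 0.35 with each library left out: -0.09 without cKO thymus library 2 and -0.07 without cKO liver library 1.

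The replicate numbers did not meet the bound set for a pairing, a correlation over 0.1 in every pair: after group means were removed, 18 pairs of libraries with the same number correlated between -0.096 and 0.08 (mean 0.023, against -0.011 in 36 other pairs). As a hint from the data and not the design, 9 of 12 libraries correlated best on average with their own number, and control and cKO liver libraries correlated between 0.072 and 0.08 with the same number and between -0.057 and -0.01 otherwise. A replicate block over the 12 libraries gave 81 genes for thymus, 71 for liver and 303 for both tissues; a block within a tissue gave 0 for thymus (limma, 714 at an unadjusted p under 0.05) and 420 for liver. In the shallow control and cKO liver libraries 1 read is worth 6.056 and 6.662 deposited units; in simulated data 16.4% of 4-fold changes were called in thymus, 14.9% in liver and 1.5% in the interaction. A named gene that an alternative's filter left out has no value there.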

Other observations

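The genes of this paragraph and the split test of the correlation between tissues were chosen only after their values were seen, while all other splits of the samples were planned. Members of the terminal effector list that passed in thymus adjusted over the list alone, and not over all genes, included the integrin gene Itgax (log2 fold change 7.78 ± 1.87, limma adjusted p = 0.064, and 0.0022 adjusted over the list alone), the galectin gene Lgals1 (4.71 ± 1.12, 0.064 and 0.0022) and Zeb2 (5.96 ± 1.47, 0.069 and 0.0023), each higher in 3 of 3 cKO thymus libraries than in any control thymus library. Integrins and adhesion receptors held 1 rise and 0 falls among 22 members, and 7 and 2 adjusted over the list alone in thymus (camera adjusted p = 0.19), and in liver 1 rise and 0 falls among 22 members, and 6 and 5 adjusted over the list alone (0.099).

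Other splits of the samples were counted for each test across genes. Over both tissues the real groups gave 297 genes and the highest other of 100 splits drawn within each tissue 12. Only the real split reached 297 (1 of 100), which argues against chance assignment of these libraries for that count. That share is the lowest the draws allow, and the libraries may be technical replicates. For the 12 genes called in both tissues (highest other 0, 1 of 100 splits) chance assignment was not tested. Only 2 of the 99 other splits had any call in thymus and any in liver, and none of these calls were of the same gene with the same sign. The fold changes of the 2 tissues over all genes correlated at 0.281, against 0.135 at the highest of the other splits (1 of 100, the real one). This argues against chance assignment of these libraries for that correlation, with the same limits. The share counts high values alone. The lowest value, -0.281, is that of the split exchanging the control and cKO liver groups, which reverses the sign by construction. The 10 splits of 6 libraries are too few for a share under 0.05: the real and highest other counts were 83 and 4 genes in thymus, 66 and 0 in liver, 79 and 0 for tissue in control cells and 29 and 0 in cKO cells. For lists they were 4 and 3 in thymus, 7 and 7 in liver (2 of 10 splits, the real one included) and 7 and 4 for tissue in control cells.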
